A study of Rattus norvegicus with 12 samples.

How the data were processed

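RNA was sequenced from T cells reactive to myelin basic protein that had been sorted from rat lungs after 7 days of pretreatment with PBS or NEO, on day 0 or day 1 after immunization through the trachea. Per the labels' protocols, lungs were digested with collagenase, leukocytes were enriched on Percoll, fluorescently labelled T cells were sorted and RNA was taken with TRI Reagent. Groups were taken from the sample labels, 3 libraries in each of 4 groups. The labels number the lungs of each group and nothing else ties libraries to animals, so p-values measure the spread between these libraries.

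The deposited tables hold whole-number counts of reads per gene, 1 table per library, with no other columns and no rows for unassigned reads. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.2a and featureCounts 1.5.0-p1 were used with the genome build rn6. The annotation release, the strand setting, the treatment of reads that fit several genes and any read filters are not given in the sources used here. Near-identical gene copies and overlapping or antisense genes can therefore share reads, and values of single identifiers carry that uncertainty.

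The totals ran from 7776335 to 16636349 counts per library, and a count of 3, the limit that a count of 0 allows, corresponded to between 0.18 and 0.386 CPM. No pair of libraries agreed within sampling noise, so each library was counted as a separate replicate. The smallest chi-square per degree of freedom over all pairs was 5.11, between the NEO and PBS day 0 libraries numbered 2.

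Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the group, which left 12449, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean for each of the 4 groups was fitted to all 12 libraries, and 6 contrasts were tested. These were NEO against PBS on day 0, on day 1 and averaged over both days, day 1 against day 0 in PBS and in NEO, and the difference of the day effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors are the log2 fold change divided by the square root of the F statistic, and 95% intervals use the moderated degrees of freedom. CPM values of genes are scaled to a library total of 1e+06 counts after TMM, and log2 CPM for components and correlations used a prior count of 2. The samples, tests, gene lists and alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data.

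The 28 gene lists fixed before the data were examined could not be tested. The files pair no identifier with a name, and 0 of the identifiers matched the gene table used here. The rule for named genes asked for the called genes with the largest fold change among genes with a symbol, a mean of at least 50 raw counts in the higher group and no overlap of CPM between groups. Without symbols it was applied to identifiers in the day comparison of PBS, and printing was limited to the first 2 that rose and the first 2 that fell. Chance makes groups of 3 libraries separate without overlap for 10% of genes.

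Measures of whole libraries were tested by exact permutation of labels within days or within arms (400 labelings, two-sided), which leaves the pairing of day 1 libraries described below out of account. The share of variation is the part of the summed squares of log2 CPM around each gene's mean that a term takes up. Whether replicate numbers pair libraries was checked by correlating deviations from group means across genes. Between NEO and PBS on day 1 the same-number correlations were 0.494, 0.628 and 0.746, all over 0.1. Each library correlated best with its own number (3 of 3), so these libraries were taken as paired by the data. These values are not separate evidence, as deviations from a group mean cancel within the group. The libraries numbered 3 thus raise the correlations among numbers 1 and 2, also those between different numbers (0.291 and 0.264). On day 0 the same-number correlations were -0.0658, 0.0902 and 0.0982. Between the days they were mixed in sign, so no pairing was used on day 0 or between the days. The NEO mean of day 0 includes replicate 1, which lay far from the others, so this check can miss pairing on day 0. By chi-square per degree of freedom, NEO day 0 replicates 2 and 3 were nearest in PBS to their own number (5.11 and 15.8). Replicate 1 was nearest to number 2 (73.8). Pairing on day 0 is therefore not excluded. The labels give no reason for the pairing of day 1.

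Alternatives were DESeq2's size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, no low-count filter, a filter of at least 50 counts in 3 libraries, only the groups compared, the replicate number as a block, and each of the 12 libraries left out in turn. The scripts were tested on simulated data drawn from the real means, library sizes and dispersions of the 12449 genes, with 200 genes changed. Each gene had 1 mean, apart from the set change, and 1 dispersion in all groups, and libraries were drawn independently. The real data hold day 1 libraries that were taken as paired, a library far from the others and a wider spread in NEO. The rates below therefore need not hold for them. For NEO against PBS on day 1, edgeR recovered 8% of the genes changed 1.5-fold, 54% at 2-fold, 86% at 4-fold and 74% at 8-fold, with 3 false calls. For the average over both days it recovered 38%, 66%, 92% and 96% with 10 false calls, and for the day comparison in PBS 8%, 50%, 88% and 88% with 6. On the same simulated counts DESeq2 made 33 false calls for NEO against PBS on day 1, 40 for the average and 38 for the day comparison, and limma voom made 4, 8 and 5.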

Results

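Gene expression was measured by RNA sequencing in T cells reactive to myelin basic protein (MBP), a protein of the myelin sheath that is used as an autoantigen in rats, after sorting of these cells from rat lungs (strain LEW/Crl). The lungs had been pretreated through the trachea for 7 days with phosphate-buffered saline (PBS) or with the antibiotic coded NEO, and cells were taken on day 0 or on day 1 after MBP was given by the same route. The 12 libraries formed 4 groups of 3, namely PBS and NEO on day 0 and PBS and NEO on day 1. The deposited tables held between 7776335 and 16636349 counts per library, with a mean of 14849173 ± 1444487 (SD, n = 6) in PBS and 11650348 ± 2649462 (SD, n = 6) in NEO. The NEO libraries were shallower by an exact permutation test within days (p = 0.035, two-sided), a difference that did not pass after adjustment over 6 such tests of library measures (adjusted p = 0.105). Of the genes listed, 24208 had a count in at least 1 library and 12449 had enough counts to be tested. Genes were named in the files by Ensembl identifiers only and none could be matched to a symbol, so genes are described here as groups, with 4 identifiers given as examples.

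The day after immunization was the main axis on which the T cells differed. The 2 days accounted for 37.1% of the variation of log2 expression between the 12 libraries (exact permutation p = 0.005, the smallest that 400 labelings allow), against 6.11% for NEO or PBS (exact permutation p = 0.395) and 4.74% for their interaction (exact permutation p = 0.625). The PBS libraries of day 0 lay close together, with correlations of 0.984 to 0.989 between replicates. NEO day 0 replicate 1 lay apart, with a mean correlation of 0.928 with the other libraries of its day, where the other 5 had means of 0.971 to 0.976. The day 1 libraries numbered 3 of both arms also stood together, away from the other 4 day 1 libraries.

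**Figure D1:**
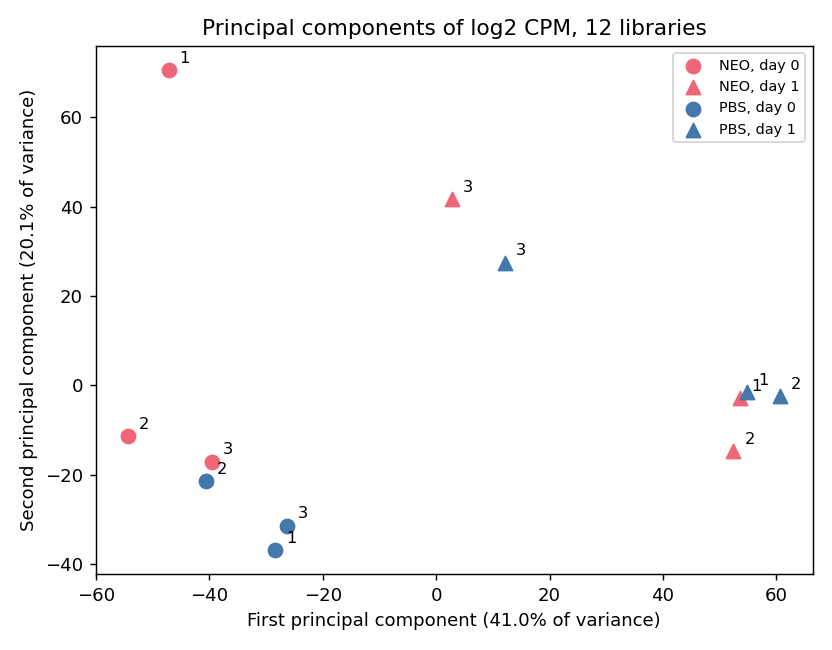
Principal components of log2 CPM (counts scaled to a common library total of 1e+06) over 12449 genes, with the first component (41.0% of the variance) on the x axis and the second (20.1%) on the y axis. Each point is a library, circles are day 0, triangles are day 1, blue is PBS, red is NEO and the digit is the replicate number; the day 1 libraries lie to the right of all day 0 libraries, and those numbered 3 lie nearest to day 0.

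How the T cells changed in control lungs within 1 day of the immunization was asked by comparing day 1 with day 0 in PBS. All day 1 libraries came after the immunization, and no library without it was taken on that day. The day effect in either arm therefore cannot be told apart from instillation, time or a batch of sorting. Many of the tested genes changed, in nearly equal numbers up and down, but the steep changes were mostly increases. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1525 genes rose and 1680 fell, 3205 in all (25.7% of the genes tested). The median log2 change was 0.85 among the genes that rose and -0.69 among those that fell. Of the genes that rose, 645 did so at least 2-fold, 315 at least 4-fold and 189 at least 8-fold, whereas 416 genes fell at least 2-fold, 52 at least 4-fold and 6 at least 8-fold. The group of 36 genes that went from a mean below 1 CPM on day 0 to at least 4 CPM on day 1 was larger than the group that went the other way, which held 4 genes. By level in 4 bins of equal size, 34.4% of the genes in the highest bin were called (median 146 CPM) and 11.5% of those in the lowest. The count was 1979 without PBS day 0 replicate 1 and 2010 without PBS day 0 replicate 2, and it was 5647 by limma voom with quality weights and 5219 when the PBS libraries were fitted alone.

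The 10 genes with the most counts in each library took a smaller part of the RNA on day 1, 6.10% ± 0.186 (SD, n = 6) against 7.51% ± 0.662 (SD, n = 6) on day 0. This difference passed an exact permutation test within arms (p = 0.005, the smallest it can give, adjusted p = 0.03 over 6 tests, two-sided). In PBS the mean share was 7.50% ± 0.264 (SD, n = 3) on day 0 and 6.14% ± 0.202 (SD, n = 3) on day 1, and in NEO 7.53% ± 1.01 (SD, n = 3) and 6.06% ± 0.202 (SD, n = 3).

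The identifiers that rose most in PBS by the naming rule were ENSRNOG00000009919 and ENSRNOG00000060831. ENSRNOG00000009919 was near absence on day 0, with 11 counts in the 3 PBS libraries together and 11 in the 3 NEO libraries, and reached 89.0 CPM ± 92.3 (SD, n = 3) in PBS and 59.8 CPM ± 44.6 (SD, n = 3) in NEO on day 1. Its log2 change was 8.39 ± 1.38 (SE) in PBS (edgeR adjusted p = 0.00168) and 7.48 ± 1.37 (SE) in NEO (edgeR adjusted p = 0.00637). Its lowest day 1 values, 10.4 CPM in PBS and 8.60 CPM in NEO, were those of the libraries numbered 3, and limma voom with quality weights did not call it in PBS (adjusted p = 0.0572) or in NEO (adjusted p = 0.201). These were the highest adjusted p over 25 alternatives in each arm, and the other 24 called it. ENSRNOG00000060831 had 3 counts on day 0 and 358 on day 1 in PBS, a ratio of 112 between the pooled CPM values, with a 95% exact counting interval of 38.1 to 547. In NEO it had 1 count on day 0 and 199 on day 1, of which none was in replicate 1, a ratio of 193 with a counting interval of 34.3 to 7668. Its edgeR adjusted p was 0.0119 in PBS and 0.0321 in NEO. In PBS the call ended without PBS day 0 replicate 2 (adjusted p = 0.0511) or 3 (adjusted p = 0.0509). In NEO it ended when NEO day 0 replicate 1, 2 or 3 was left out (adjusted p = 0.0621, 0.0988 and 0.0646), without PBS day 0 replicate 3 (adjusted p = 0.0506) and without NEO day 1 replicate 2 (adjusted p = 0.108). It also ended with the replicate number as a block (adjusted p = 0.0525), with the NEO libraries fitted alone (adjusted p = 0.153) and by limma voom (adjusted p = 0.393). Over its 25 alternatives the adjusted p ran from 0.00118 to 0.0511 in PBS and from 0.00534 to 0.393 in NEO. Counting intervals here cover counting error only.

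The identifiers that fell most in PBS were ENSRNOG00000052880 and ENSRNOG00000008001, both of low level. ENSRNOG00000052880 went from 3.56 CPM ± 0.116 to 0.298 CPM ± 0.149 in PBS (SD, n = 3), where it fell by 3.53 ± 0.77 (SE) on the log2 scale (edgeR adjusted p = 0.00742), a call kept in each library left out. In NEO it went from 3.04 CPM ± 2.12 to 0.440 CPM ± 0.405 (SD, n = 3) and fell by 2.68 ± 0.75 (SE, edgeR adjusted p = 0.0372). That call in NEO ended in 9 of the 12 fits that left out a library, with an adjusted p of 0.12 without NEO day 1 replicate 1 and a range of 0.00289 to 0.186 over 24 alternatives. ENSRNOG00000008001 went from 4.17 CPM ± 1.75 to 0.485 CPM ± 0.265 in PBS (SD, n = 3) and fell by 3.09 ± 0.82 (SE, edgeR adjusted p = 0.0188). Its call in PBS ended without PBS day 0 replicate 3 (adjusted p = 0.0647), PBS day 1 replicate 2 (adjusted p = 0.0722) or PBS day 1 replicate 3 (adjusted p = 0.051). In NEO it was at 1.85 CPM ± 1.57 on day 0 and 0.369 CPM ± 0.103 on day 1 (SD, n = 3), which was not called with all libraries (edgeR adjusted p = 0.101) and was called without NEO day 0 replicate 1 (adjusted p = 0.00669). Over 24 alternatives the adjusted p ran from 0.000786 to 0.0722 in PBS and from 0.00669 to 0.265 in NEO.

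**Figure D2:**
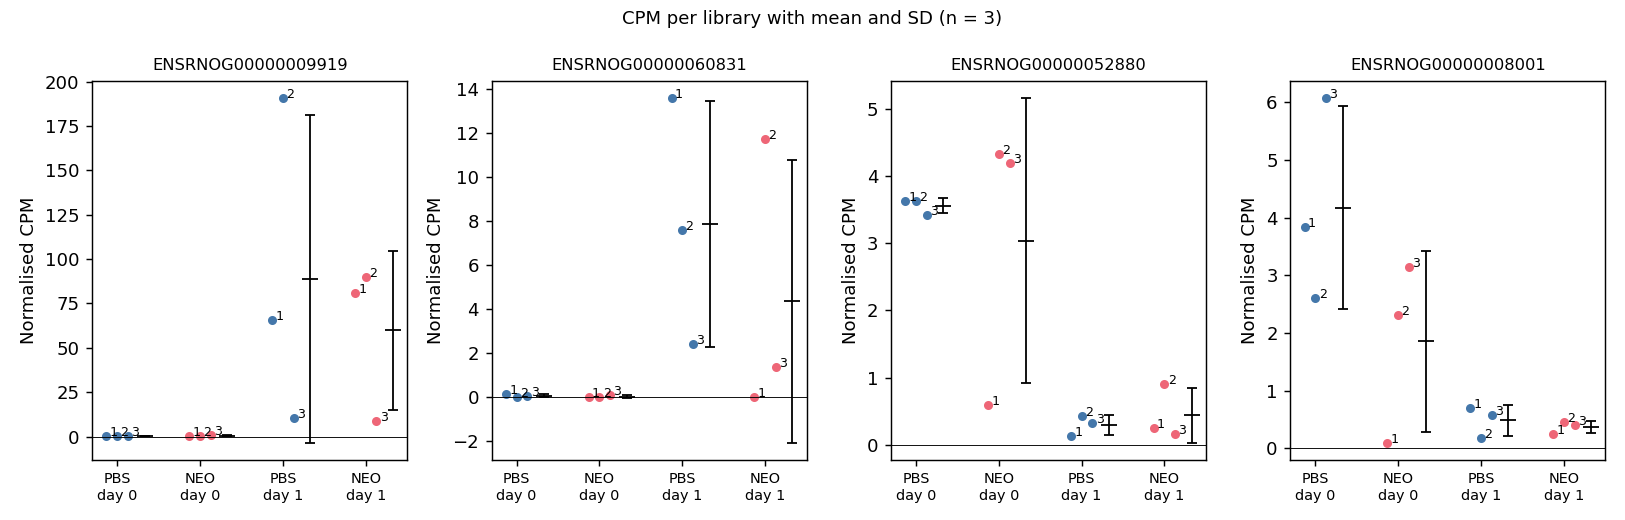
Normalised CPM (y axis) of the 4 identifiers in each library, by group (x axis), with the replicate number beside each point and the mean ± SD of 3 libraries as a bar to the right. The 2 identifiers on the left rose from under 1 CPM on day 0, to as much as 191 CPM for ENSRNOG00000009919; the 2 on the right fell from 3.56 and 4.17 CPM in PBS on day 0.

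The same question in antibiotic-treated lungs was answered by day 1 against day 0 in NEO, where 911 genes rose and 913 fell, 1824 in all (edgeR quasi-likelihood, Benjamini-Hochberg adjusted). As in PBS, the steep changes were mostly increases, 246 genes rising and 9 falling at least 4-fold, and 83 rising and 1 falling at least 8-fold. The median log2 change was 1.18 among the genes that rose and -0.63 among those that fell. The count was 872 without NEO day 1 replicate 1 (566 up, 306 down) and 993 without NEO day 0 replicate 2 (503 up, 490 down). Without NEO day 1 replicate 3 it was 1445, with 930 up and 515 down. It was 122 when the NEO libraries were fitted alone (103 up, 19 down) and 2739 by limma voom with quality weights (1239 up, 1500 down). Within groups the median SD of a gene's log2 CPM was 0.297 on day 0 and 0.232 on day 1 in NEO. In PBS it was 0.131 and 0.157. On day 0 NEO replicates 2 and 3 correlated at 0.986, where PBS replicates had 0.984 to 0.989. NEO replicate 1 correlated with them at 0.934 and 0.925, so much of the NEO spread of day 0 lay in 1 library. The fit of all 12 libraries shares its estimate of the spread between the arms, with a median SE of 0.198 in NEO and 0.197 in PBS. The NEO count of that fit therefore rests in part on the spread of the PBS libraries. With DESeq2's size factors 1003 rose and 730 fell, and with upper-quartile factors 864 and 1082, so the balance of rises and falls depends on the library set and the scaling.

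The day effect went the same way in both arms for nearly all genes called in either, and the arms share no library. Of the 1525 genes that rose in PBS, 97.8% were also higher on day 1 in NEO, with a median log2 change of 0.63 there, and of the 1680 that fell in PBS 98.7% were lower in NEO, with a median of -0.46. Of the genes called in NEO, 903 of the 911 risers and 904 of the 913 fallers had the same direction in PBS, with medians of 1.10 and -0.67. In both arms 739 genes rose and 746 fell, where independent lists would share 112 and 123, and 0 genes were called in opposite directions. Genes in the highest bin by level were called more often than those in the lowest, in PBS (34.4% against 11.5%) and in NEO (18.2% against 7.36%). The 2 lists also share 1 estimate of the spread. Level and shared spread can raise the overlap above 112 and 123 without a common day effect, by an amount that was not estimated. At least 4-fold changes in both arms were found for 180 of the risers and 3 of the fallers, and 4 genes went from below 1 CPM to at least 10 CPM in both arms. Across all tested genes, which are not independent replicates, the 2 day effects correlated at r = 0.74 (Spearman's rho = 0.73), at r = 0.84 over the 8377 genes with a mean of at least 10 CPM and at r = 0.241 without a low-count filter. Same-numbered day 1 libraries of the arms deviated together, which raises such overlaps and correlations without a common day effect, by an amount that was not estimated. The 1485 genes called in both arms became 807 without NEO day 1 replicate 1, 830 without NEO day 0 replicate 2 and 2373 by limma voom.

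Together the 739 genes that rose in both arms went from 3.69% ± 0.0772 to 8.24% ± 0.231 of all counts in PBS, and from 3.77% ± 0.243 to 7.53% ± 0.702 in NEO (SD, n = 3). The 746 genes that fell in both arms took 11.7% to 12.2% of the counts in the 3 PBS libraries of day 0 and 7.15% to 7.41% on day 1. In NEO their mean share went from 12.1% ± 1.02 to 8.17% ± 0.619 (SD, n = 3). These genes were chosen on the same libraries, so the shares describe their weight in the RNA and are no further test.

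**Figure D3:**
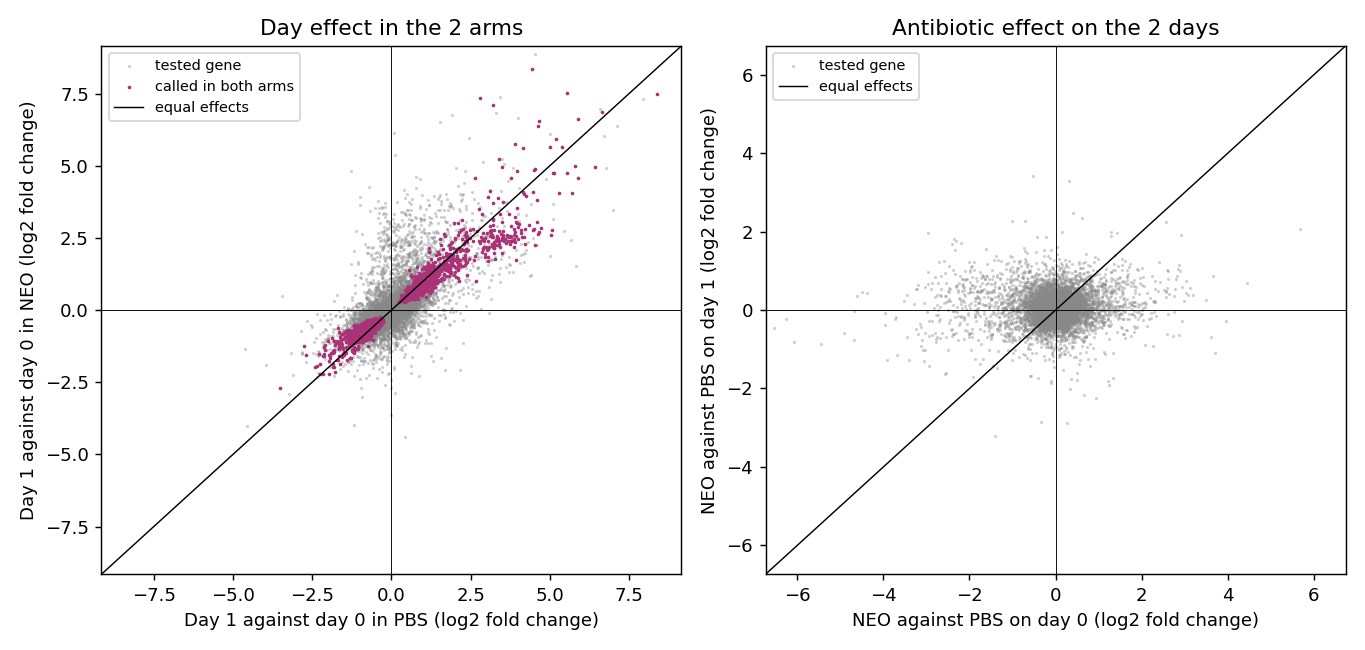
Left, log2 fold change from day 0 to day 1 in PBS (x axis) and NEO (y axis) for 12449 genes (grey), with the 1485 genes called in both arms in purple; all of these lie in the lower left and upper right corners. Right, log2 fold change of NEO against PBS on day 0 (x axis) and day 1 (y axis) for the same genes (r = 0.06, below 0 when any of 4 libraries is left out); the diagonal lines mark equal effects.

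Whether the antibiotic changed the response to the immunization was asked by the difference of the day effects, for which edgeR called 0 genes. An unadjusted p under 0.05 was found for 608 genes, where chance gives 622, and the smallest adjusted p was 0.863. That number was 1413 by limma voom. With 1 library left out it ran from 322 (PBS day 0 replicate 1) to 1489 (NEO day 1 replicate 3), so its closeness to chance depends on the setting. DESeq2 and limma voom also called 0. The 95% interval of the difference lay within 2-fold for 57.2% of the genes, so for the rest a 2-fold difference was not excluded. The larger number of genes called in PBS than in NEO is therefore not a tested difference between the arms. Over the 4736 genes called for the day effect averaged over the arms, the median size of the log2 change was 0.51 in NEO and 0.64 in PBS. The median difference per gene, NEO minus PBS, was -0.13, which did not pass an exact permutation test of the arm labels within days (p = 0.105, two-sided, 400 labelings). With the day 1 labels exchanged only between libraries of the same number, a test chosen after seeing the data, the exact permutation p was 0.15 (160 labelings).

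As a share of counts, the steepest risers of PBS were higher in NEO day 0 replicate 1 than in the other day 0 libraries. The 189 genes that rose at least 8-fold in PBS took 0.0796% to 0.0931% of the counts in the other 5 day 0 libraries, 0.375% in NEO day 0 replicate 1 and 0.944% to 1.32% in the day 1 libraries. Gene by gene, 122 of the 189 (64.6%) were higher in it than in each other day 0 library, against 34.1% of all genes. In NEO 188 of these 189 genes were higher on day 1 and 135 were called. When genes were chosen instead by a called rise of at least 8-fold on average over the arms, 161 genes had a median log2 change of 3.06 in NEO and 3.38 in PBS, which did not differ past the threshold (exact permutation p = 0.775, two-sided). For the 412 genes that rose at least 4-fold on average the medians were 2.53 in NEO and 2.49 in PBS (exact permutation p = 0.855). The median difference per gene, NEO minus PBS, was -0.259 for the 161 genes and -0.105 for the 412, of which 54.4% rose more in PBS.

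A further group of genes separated the day 1 libraries numbered 3 from the others, in both arms. Chosen after the data were seen, 204 genes with a mean of at least 10 CPM before TMM scaling were at least 2-fold lower in the library numbered 3 than in the mean of the other 2 libraries of its arm in both arms, 0 genes were at least 2-fold higher in both, and 1 gene went in opposite directions. These 204 genes took 1.29% to 2.39% of the counts in the day 1 libraries numbered 1 and 2, 0.287% and 0.291% in those numbered 3, and 0.372% to 0.699% on day 0. Of the 204, 33 had been called as rising in PBS and 39 in NEO. With both day 1 libraries numbered 3 left out, a choice made after seeing the data, 2738 genes were called for the day effect in PBS (1414 up, 1324 down) and 1513 in NEO (1056 up, 457 down).

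**Figure D4:**
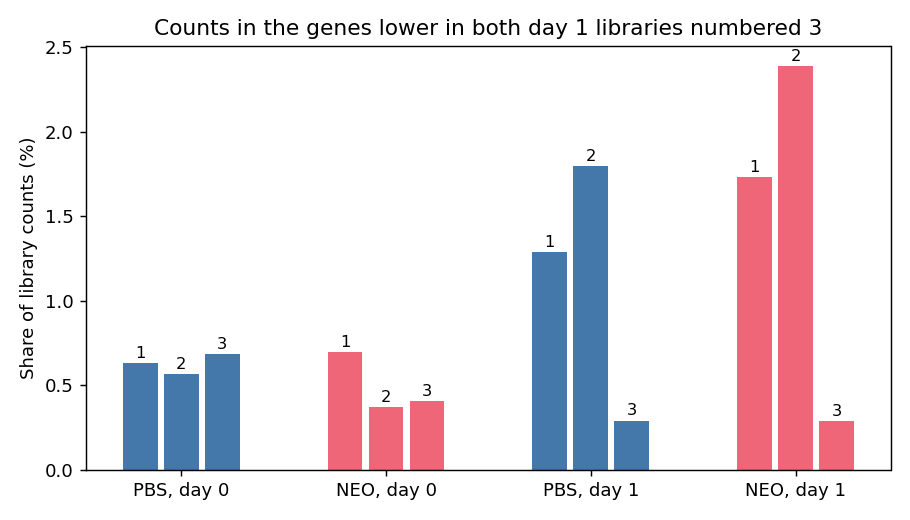
Share of each library's counts (y axis, percent) in the 204 genes that were lower in both day 1 libraries numbered 3, by group (x axis), with the replicate number above each bar; bars are single libraries, blue for PBS and red for NEO. The 4 day 1 libraries numbered 1 and 2 lie between 1.29% and 2.39%, the libraries of day 0 and those numbered 3 of day 1 at 0.699% or less.

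What the antibiotic did to the T cells before the immunization took effect was asked by NEO against PBS on day 0. No gene group could be set apart, as edgeR called 0 genes. The number with an unadjusted p under 0.05 was 832 (6.68%, where chance gives 622 genes), and the smallest adjusted p was 0.292. With 1 library left out, that number ran from 395 (PBS day 0 replicate 1) to 1635 (NEO day 0 replicate 3), on both sides of chance. The gene with the smallest p had a log2 difference of 1.62 ± 0.25 (SE), with means of 2.30 CPM in PBS and 7.09 CPM in NEO. The 95% interval of the difference lay within 2-fold for 69.1% of the genes. DESeq2 called 53 genes, 51 of them higher in NEO, limma voom called 0, edgeR without a low-count filter called 13, all higher in NEO, and edgeR without PBS day 0 replicate 2 called 3.

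On day 1, NEO against PBS again gave 0 genes by edgeR in the fit of all 12 libraries, with 517 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.995. The number at an unadjusted p under 0.05 was 1745 by limma voom, and 2093 in the paired fit described below. With 1 library left out it ran from 272 (NEO day 1 replicate 2) to 1448 (NEO day 1 replicate 3). The 95% interval lay within 2-fold for 71.1% of the genes. DESeq2 called 12 genes, 10 of them higher in NEO, and limma voom called 0. On day 1 libraries were taken as paired by replicate number, since same-numbered NEO and PBS libraries deviated together from their group means. Libraries numbered 1 and 2 also correlated across numbers between the arms (r = 0.291 and 0.264), as the outlying libraries numbered 3 would give. With the replicate number as a block in the fit of all 12 libraries the count stayed at 0, also when the block was set within each day. The 6 day 1 libraries were also fitted alone with the block, chosen after the data were seen, which left 2 residual degrees of freedom. This fit by edgeR called 80 genes, 52 higher and 28 lower in NEO, with a median size of 0.74 on the log2 scale. Of these, 12 were at least 2-fold higher and 4 at least 2-fold lower. The same paired fit called 62, 111 and 1582 genes with pair 1, 2 or 3 left out, 209 by DESeq2 and 869 by limma voom.

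The effect of NEO common to both days, tested with 6 libraries against 6, also gave 0 genes by edgeR, with 686 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.103. The gene with that value had a log2 difference of 1.40 ± 0.19 (SE), with means of 38.5 CPM in PBS and 126 CPM in NEO on day 0 and of 58.3 CPM and 124 CPM on day 1. The number of genes at an unadjusted p under 0.05 was 1296 by limma voom. With 1 library left out it ran from 430 (PBS day 0 replicate 1) to 1518 (NEO day 0 replicate 3), where chance gives 622. The 95% interval lay within 2-fold for 80.4% of the genes. The NEO effects of the 2 days, which share no library, correlated at r = 0.06 across genes, which are not independent replicates, and had the same sign for 50.7% of the genes. With 1 library left out r ran from -0.0944 without NEO day 0 replicate 1 to 0.29 without NEO day 1 replicate 2. It was also below 0 without NEO day 1 replicate 3 (-0.0821), PBS day 1 replicate 1 (-0.0245) or PBS day 1 replicate 2 (-0.0373), and it was 0.166 without PBS day 1 replicate 3 and 0.101 without NEO day 0 replicate 3. DESeq2 called 73 genes, 71 of them higher in NEO, limma voom called 2, and edgeR without a low-count filter called 24. Leaving out NEO day 1 replicate 1 gave 18 genes, PBS day 0 replicate 2 gave 5 and NEO day 0 replicate 1 gave 3, all higher in NEO.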

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

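The tests by splits of the libraries and those of a mislabelled day, of day 1 RNA in a day 0 library, of NEO day 0 replicate 1 as the reason for fewer calls in NEO, of a fixed added profile, and of the size of the day effect were chosen after the values they use had been seen; the others were set before theirs, except that 1 limit, named below, was given a margin afterwards. Of 12 sets of 6 libraries tested for a value far from the rest, 2 exceeded Dixon's 95% limit, and chance flags about 1 in 20. NEO day 1 replicate 2 had 19384 genes with a count, where the other NEO libraries had 15282 to 16819, a gap of 0.6253 of the range and just over the limit. NEO day 0 replicate 1 had a mean correlation of 0.928 with the other day 0 libraries, where the lowest of those was 0.971, a gap of 0.894 of the range.

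The tables argue against 3 explanations of the distance of NEO day 0 replicate 1. With all libraries thinned to 7776335 counts its mean correlation still lay 0.0392 below the lowest of the others, which depth does not give. It correlated more highly with day 0 than with day 1 libraries, by 0.0244, which argues against a day 1 library under another label. Of 599 genes outside the range of the other 5 and at least 4-fold off, 43.6% were higher, where RNA added from other cells as the whole cause would need most to be higher. Left open are a partial loss of transcripts, as 56.4% of these genes were lower, though after thinning it had 15341 genes with a count and another day 0 library had 15282, and some day 1 RNA or some T cells already changed before day 1, as 64.6% of the 189 steepest PBS risers were higher in it than in each other day 0 library (34.1% of all genes were), less than a mixture of whole libraries may need.

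The day 1 libraries numbered 3 deviated together from their group means (r = 0.746 across genes), which depth does not explain, since r was 0.726 after thinning. Of the 204 genes lower in both, 26.0% lay between day 0 and the other day 1 libraries, as a smaller advance from the day 0 state would need. While 151 lay below day 0, 98 lay within 2-fold of it, and the median log2 difference from day 0 was -0.79 over the 204. The genes were chosen for low values in these same 2 libraries, which favours values below day 0, so these counts do not decide. Over 1790 genes with no day difference the differences from the other day 1 libraries still correlated at 0.507. A smaller advance alone would not give this. Deviations shared by the libraries numbered 1 and 2 enter the differences of both arms and can also give it, so the value does not decide. It is past the limit of 0.5 set beforehand for excluding a smaller advance, but by less than its spread. That spread is a standard error over genes, which are not independent replicates. That margin was required only after the value was seen, so a smaller advance stays open for all genes. Steep risers, chosen with these libraries among the others, differed by list. The 161 genes that rose at least 8-fold on average over the arms took 0.661% and 0.664% of the counts in these 2 libraries and 0.749% to 1.01% in the other 4, at a mean log2 CPM of 2.49 and 2.55 against 3.74 to 4.21. The 189 steepest PBS risers took 1.08% and 1.13% against 0.944% to 1.32%. The difference of each library numbered 3 from the other day 1 libraries of its arm was regressed on the other arm's day effect. This used 8379 genes with a mean of at least 10 CPM before TMM scaling. The day effect took up 32.0% of the variance in PBS (slope -0.393) and 1.86% in NEO (slope -0.116). A smaller advance would give this sign. Deviations shared by same-numbered libraries would give it too, so these values do not decide. For a source of RNA with 1 fixed profile in the other 4 day 1 libraries, profiles of the 204 genes were compared between numbers. They correlated at 0.874 and 0.907 between libraries of the same number and at most 0.773 between different numbers, 0.101 lower. The 2 libraries numbered 3, where these genes are low, also correlated at 0.946 with each other and at most 0.735 with other numbers. Such a gap thus arises without the added source, so this test cannot decide. Added cells of 1 or several profiles that passed the sorting of labelled T cells, or a shared day of sorting for each number, remain possible. Purity was not measured here, the labels name no batch, and no biological explanation was tested.

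Fewer genes were called between the days in NEO (1824) than in PBS (3205). Depth does not account for this, as the ratio was 1.85 with all libraries thinned, and neither does NEO day 0 replicate 1 alone, as the ratio stayed at 1.82 or more with it and any 1 PBS day 0 library left out. A smaller day effect after the antibiotic may contribute but cannot be told apart from chance with these libraries. The exact permutation p was 0.105 with the arm labels exchanged freely within days, which ignores the pairing of day 1, and 0.15 with those of day 1 exchanged only within numbers.

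Other splits of the same libraries were set beside each count. In the day comparisons the real split called 3205 genes in PBS and 1824 in NEO, and the highest of the other 9 splits called 0 in each. Each of those 9 mixed the days in both groups, which turns a day difference into spread within groups and keeps counts low. They therefore say little about chance. In addition, 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05. For NEO against PBS the real count was 0 on each day, in the average over both days and in the difference of the day effects. Any split reaches 0, so the splits that did (10 of 10 on each day, 100 of 100 drawn for the average and for the difference) say nothing about chance; the highest of the others called 0 on day 0, 1 on day 1, 1 in the average and 0 in the difference. For the paired fit of day 1, which called 80 genes, the other 3 of 4 ways to flip the arms within pairs called 0, and 4 are too few for a share under 0.05.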

How the results depend on the processing

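Settings that leave out more than 1 library, the block within days and the fits of 1 day's libraries were chosen after seeing the data; all others were fixed before. Of the alternative counts of called genes, 128 stayed within 1.5 times the reported one and 31 did not. The 128 include each count of 0 that stayed at 0, for NEO against PBS on each day, their average and the difference. They therefore say less about the counts above 0. The cause of a move was not tested. Fits with fewer libraries have less to estimate the spread from, but the counts of the arms fitted alone moved in opposite directions. Replicates were more spread in NEO than in PBS, as given above, on day 0 in large part through NEO day 0 replicate 1. Other scalings moved the median of all genes by under 0.1 on the log2 scale and changed no count by over 1.5 times.

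For NEO against PBS on day 0 (0 genes), DESeq2 gave 53, no filter 13, setting A (both day 1 libraries numbered 3 and NEO day 0 replicate 1 left out) 6, and setting B (NEO day 0 replicate 1 and PBS day 0 replicate 2 left out) 4; leaving out 1 library gave 0 to 3. For NEO against PBS on day 1 (0), DESeq2 gave 12 and leaving out 1 library 0; the day 1 libraries alone with the replicate block gave 80, by DESeq2 209, by voom 869, and 62, 111 and 1582 with pair 1, 2 or 3 left out, each with 1 residual degree of freedom. For the average over both days (0), DESeq2 gave 73, voom 2, no filter 24, setting A 1, setting B 20, and leaving out 1 library 0 to 18. For the difference of the day effects (0), setting A gave 6, and leaving out 1 library 0.

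For day 1 against day 0 in PBS (3205), voom gave 5647, the PBS libraries alone 5219 and setting A 4880; leaving out 1 library gave 1979 to 4408. In NEO (1824), voom gave 2739, the NEO libraries alone 122 and setting A 2985; leaving out 1 library gave 872 to 2063. With the replicate block in the fit of all 12, the paired counts were 0 for NEO against PBS on each day, their average and the difference, 3395 for the day effect in PBS and 1868 in NEO, so that block changed no count by over 1.5 times; ENSRNOG00000060831 lost its call in NEO (adjusted p = 0.0525).

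The 4 printed identifiers kept their direction under every alternative run, with 30 values that lost and 5 that gained a call. Across genes the correlation of the 2 day effects ran from 0.241, without a filter, to 0.81, and that of the NEO effects of the 2 days from -0.139 to 0.29. Alternatives of the gene list tests were not run, since no list could be formed. Depth limits genes near 0.18 to 0.386 CPM, where 3 counts is the floor.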

Other observations

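The genes set apart by NEO in the paired fit of day 1 had a median of 62.2 CPM among the 80, and 52 were higher in NEO. Among the 4 bins of tested genes by level, this median lay between that of the highest bin (146 CPM) and that of the bin below it (45.3 CPM). On day 0, in other libraries and without pairing, 59 of the 80 differed between NEO and PBS in the same direction, and 0 were called there. For these 80 genes, the hypothesis of an antibiotic effect shared by both days was tested by this count after the genes were seen. It stays open, because 4 of the 20 labelings of the day 0 libraries gave at least as many genes in that direction (exact permutation p = 0.2, one-sided), up to 64, and genes that vary together make such counts uneven.

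Across the 204 genes that were low in both day 1 libraries numbered 3, the NEO and PBS profiles of day 1 correlated at 0.946 for number 3, 0.907 for number 1 and 0.874 for number 2, while libraries of the same arm and different numbers correlated at 0.517 to 0.773. The 204 genes had a median log2 difference of -3.25 in the libraries numbered 3 against the other day 1 libraries.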
